A study of Rattus norvegicus with 9 samples.

How the data were processed

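RNA was measured in skin of 9 male Wistar rats, 5 of 6 months and 4 of 24 months. RNA was purified with a column kit (Qiagen RNeasy) and polyadenylated RNA was made into libraries with Illumina's TruSeq RNA v2 kit, per the labels' protocols. That kit does not mark the strand, and how reads were assigned to genes is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The submitters' processing notes name BWA, with no version; the genome build, the annotation and the counting rule are not given in the sources used here, and no genome coordinates are printed. The deposited values are raw read counts per gene symbol, not normalized, in 1 table with a column per sample. The table holds 23480 symbols in capitals and no row that names no gene. The body site of the skin is not given in the sources used here.

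Columns were matched to samples by their titles, and groups were taken from the labelled age. The series' design text says that the samples are different animals. Depth was taken as the total count per sample, 17.3 to 34.1 M (M, a count of 1000000). Symbols were matched by name to a RefSeq gene table of the rat assembly GRCr8, used for names only: 16432 were a current symbol and 18919 a current symbol or a synonym. Pairs of samples within a group were checked for repeated libraries by a chi-square test of their counts over genes. The replicate numbers in the labels name different animals and were not taken as pairs.

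Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 14933. Old and young skin were compared with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, edgeR 4.0.16 in R 4.3.3) on all 9 samples, with TMM normalization, no covariate and Benjamini-Hochberg adjustment at 0.05. Fold changes are old over young, on the log2 scale with their SE. The SE was worked back from the test, as the absolute log2 fold change over the square root of its F statistic. It is therefore approximate, above all for genes with few counts. CPM values are TMM-normalized and given as mean ± SD (n = 5 young, n = 4 old).

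Before the data were examined, 39 gene lists were fixed for cell types of skin and tissues a biopsy can hold, and for processes of ageing, with 1205 entries. Of these entries, 1143 matched a symbol of the table by the same name, 13 by another name and 49 did not match. The list of mitochondrially encoded genes had no member in the table, so 38 lists were tested, with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. A list's score in a sample is the mean log2 CPM of its tested members. Scores and shares were compared with exact permutation tests over the 126 splits into 5 and 4, whose smallest two-sided p is 0.00794. A list of genes of regional identity was written after the files were seen and before its values were looked at.

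The genes named were chosen by a rule fixed beforehand. First, these were the 12 largest rises and 12 largest falls among genes past the threshold with a symbol that is not a placeholder, a mean CPM of at least 1 and groups that do not overlap. Second, these were up to 4 called members of each list, those with the smallest adjusted p. Last, whatever their values, these were Cdkn2a, Col1a1, Col3a1 and Mki67. The rule gave 133 genes with values in the main test; 31 more were named after their values were seen.

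The test was tried on simulated counts drawn from the real means and library sizes, with 200 genes changed by 2-fold or 4-fold and the 30 genes of a list raised by 0.70 on the log2 scale. Over 14827 genes it recovered 34% of genes changed by 2-fold and 87% of those changed by 4-fold, and 9 of the 30, with 2 of 132 calls among unchanged genes. Ratios of pooled counts carry exact binomial intervals at 95%, which cover counting error only.

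The alternatives were DESeq2 1.42.0, limma-voom with and without sample weights, other scalings, other filters, a replicate block, the muscle, hair or adipocyte score as covariate, a stricter threshold, a required change of over 1.5-fold, an estimated correlation or fry for the lists, lists without shared genes, and leaving out each library. Libraries thinned to the smallest total, and the muscle and hair scores together as covariates, were added after seeing the data. Figures were drawn with matplotlib 3.10.9.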

Results

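Polyadenylated RNA was sequenced from the skin of 9 male Wistar rats, an outbred albino laboratory strain. Of these, 5 animals were young (6 months) and 4 were old (24 months), and the design compares the skin of the 2 ages. Read counts were given for 23480 gene symbols, of which 3996 had no count in any sample and 14933 were kept for testing. Total counts ran from 17.3 to 20.2 M (M, a count of 1000000) in the young samples (mean 18.9 ± 1.27 M, SD, n = 5) and from 20.1 to 34.1 M in the old samples (27.2 ± 6.01 M, n = 4). The old libraries were thus deeper (two-sided exact permutation p = 0.0159). Spearman correlations across genes lay between 0.962 and 0.986 within the groups. Pairs of samples within a group differed by at least 30.6 times the sampling noise (chi-square per degree of freedom), so each was counted as a separate sample.

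In old skin, 27 of 29 macrophage markers, 18 of 24 fat cell markers and 20 of 39 elastic fibre and proteoglycan genes rose, while 18 of 25 genes of cholesterol synthesis, 12 of 28 of the sebaceous gland and 13 of 38 of the epidermal barrier fell. Of 38 gene lists, 26 passed a test with a preset correlation between genes and 0 passed with an estimated one (smallest adjusted p 0.101). Of the genes tested, 1437 rose and 659 fell (edgeR quasi-likelihood test, adjusted p under 0.05), which is 14.0% of the genes. Among the calls, 867 rose and 290 fell by at least 2-fold. The groups did not overlap in 2465 of the 14933 tested genes (16.5%, where chance gives 1.59%). Higher genes made up 68.6% of the calls. With library totals alone as the scaling, 1956 genes rose and 312 fell, a share of 86.2%, and the median log2 fold change of all genes moved from -0.05 to 0.11. The number that fell depended on single libraries: it was 350 without young replicate 2, 371 without young replicate 3, 316 without young replicate 4 and 236 without old replicate 4.

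The largest rises included Lep, which encodes the fat hormone leptin, and Myh4, which encodes the myosin heavy chain of fast type IIB muscle fibres. Lep went from 4.48 ± 5.75 counts per M (CPM; SD, n = 5) to 178 ± 107 (n = 4), and Myh4 from 385 ± 159 to 14158 ± 9835 CPM. The 12 largest rises among genes with non-overlapping groups also held Sln (sarcolipin, a regulator of the muscle calcium pump; log2 fold change 4.88 ± 0.71, SE), Pck1, Adipoq, Plin1, Klf14, Kcnj3, Ankef1, Tmem179, Cdh26 and Mrgprg, at 4.13 to 4.58. The call of Mrgprg, a member of the Mas-related receptor family, was lost without young replicate 3, 4 or 5 (adjusted p up to 0.0669), and its log2 fold change was 2.56 without old replicate 2. The 12 largest falls held the pigment genes Tyrp1 (-9.33 ± 1.84) and Dct (-5.34 ± 1.28), the slow-muscle genes Myh7, Tnnc1, Tnni1 and Myl2, and Serpina5 (-5.16 ± 0.65), Chga (-4.15 ± 0.64), Nhlh2, Cdh16, Tceal7 and Bin2a. Serpina5 had 243 counts over the young libraries and 8 over the old, a pooled ratio of 39.5 (95% exact interval 19.7 to 92.5, counting error only). Nhlh2 (-3.85 ± 1.10, adjusted p = 0.0447) kept its call without young replicate 1 or old replicate 2 and lost it without any of the others (adjusted p up to 0.115); it was -6.64 without old replicate 2.

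**Figure D1:**
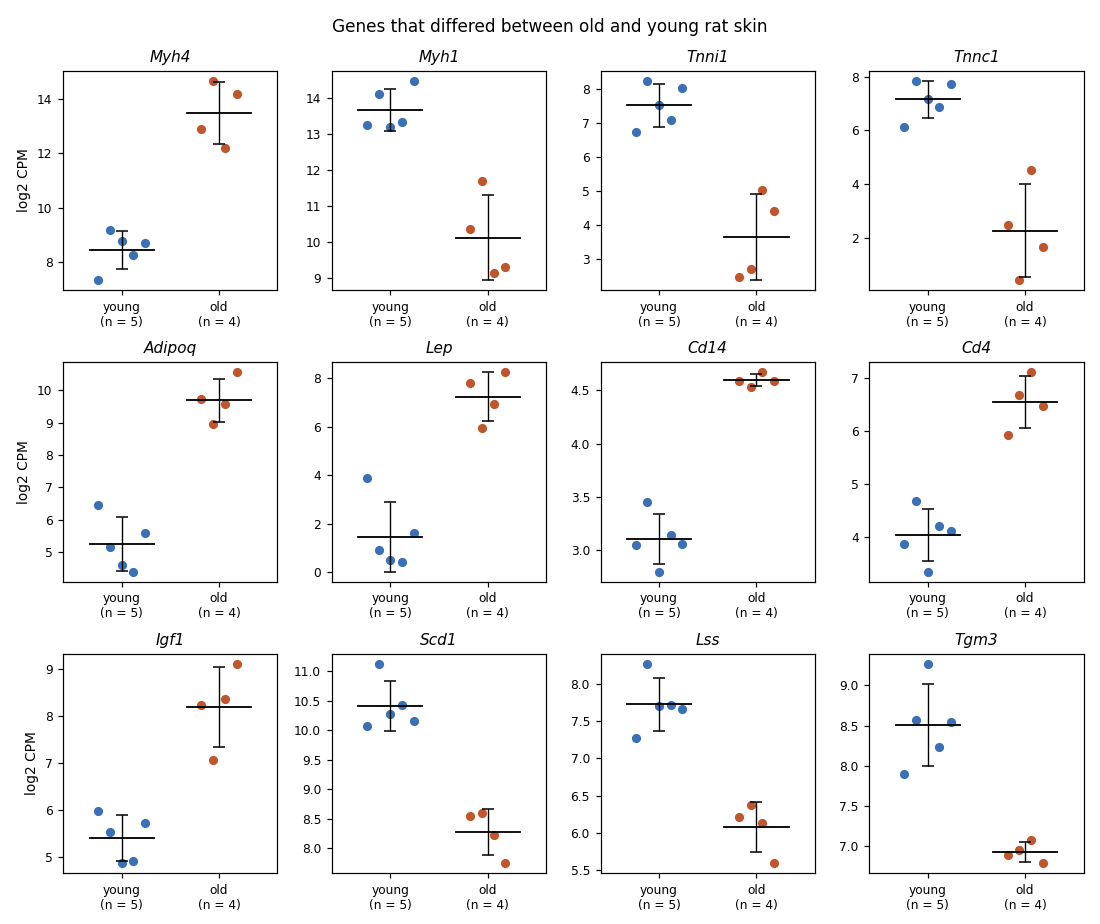
Log2 CPM of 12 called genes in each sample of young (blue) and old (orange) skin; lines are group means and bars are 1 SD of log2 CPM (n = 5 and n = 4). The groups did not overlap in any of the 12 panels, and Lep rose from a mean of 4.48 to 178 CPM.

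Fat cell genes rose together. Of 24 adipocyte markers tested, 18 rose and 0 fell; adjusted over the list alone, 18 rose and 1 fell. Adipoq, which encodes the fat hormone adiponectin, went from 43.5 ± 27.3 to 902 ± 434 CPM, Plin1, which encodes a coat protein of lipid droplets, from 15.6 ± 11.2 to 272 ± 140, and Cfd, which encodes adipsin, from 195 ± 80.4 to 1480 ± 527. The median log2 fold change of the list was 2.21 (camera adjusted p = 6.27e-12, and adjusted p = 0.143 with an estimated correlation). The list took 0.211 ± 0.0297% of all counts in young skin and 0.856 ± 0.307% in old skin (two-sided exact permutation p = 0.00794, the smallest that 5 against 4 samples allow). Of 23 growth hormone, insulin-like growth factor and imprinted growth genes, 6 rose and 0 fell (8 and 1 adjusted over the list alone; median 0.70, adjusted p = 0.000595, and adjusted p = 0.178 with an estimated correlation). They included Igf1 (insulin-like growth factor 1), from 44.3 ± 14.7 to 330 ± 173 CPM, and the imprinted genes Plagl1 (log2 fold change 3.03 ± 0.39), Mest (3.60 ± 0.70) and Nnat (3.02 ± 0.45). With the adipocyte score as a covariate, the growth list's median was 0.38 (adjusted p = 0.767) and that of the adipocyte list, whose genes make up the score, -0.09 (adjusted p = 0.691). In that model 0 genes passed the edgeR test in either direction, and 482 rises and 133 falls reached an unadjusted p under 0.05. That score did not overlap between the ages, and the median SE went from 0.20 to 0.57 with it in the model; no other tool was run on this model.

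Markers of macrophages and monocytes rose almost throughout: 27 of 29 members tested rose and 0 fell, with the same counts adjusted over the list alone. Cd14, a receptor for bacterial lipopolysaccharide, went from 8.67 ± 1.45 to 24.2 ± 0.938 CPM and Lyz2 (lysozyme) from 41.8 ± 7.86 to 137 ± 30.2. Aif1 and Laptm5 rose by 1.87 ± 0.23 and 1.32 ± 0.15 on the log2 scale. The list's median log2 fold change was 1.79 (adjusted p = 4.45e-20, and adjusted p = 0.101 with an estimated correlation). Of 26 complement and acute phase genes, 18 rose and 0 fell (20 and 0 adjusted over the list alone; median 1.61, adjusted p = 1.12e-11, and adjusted p = 0.119 with an estimated correlation). C1qc, C2, C6 and Serping1 led them, and C2 went from 66.4 ± 23.3 to 266 ± 36.9 CPM. The adipocyte list's share of counts was also higher in old skin, 0.856% against 0.211% in young, as were both lists and those of the next 3 paragraphs. Within old skin the macrophage score did not follow that share. Replicate 4 had a share of 1.16% and a score of 4.11, and replicate 3 had 0.606% and 4.85.

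Many T and NK cell, mast cell and antigen presentation genes also rose. Of 25 T and NK cell markers, 14 rose and 1 fell (19 and 1 adjusted over the list alone; median 1.33, adjusted p = 1.28e-09, and adjusted p = 0.101 with an estimated correlation). Cd4, which rat monocytes and macrophages carry as well as helper T cells, went from 17.3 ± 5.74 to 97.7 ± 32.0 CPM, and Prf1 (perforin) from 0.50 ± 0.0302 to 1.57 ± 0.210. Cd28 and Il2rb rose by 2.26 ± 0.34 and 1.57 ± 0.25 on the log2 scale. The member that fell, named after its value was seen, was Cd6 (-2.73 ± 0.48). Of 12 mast cell markers, 8 rose and 0 fell, over all genes and adjusted over the list alone (median 2.04, adjusted p = 4.26e-08, and adjusted p = 0.101 with an estimated correlation). Fcer1a, a chain of the high-affinity IgE receptor, went from 0.276 ± 0.103 to 3.78 ± 1.77 CPM and Cma1 (chymase) from 5.54 ± 1.12 to 27.4 ± 10.8; Cma1 and Mcpt1l1 belong to a protease family whose members share reads, so their single values are uncertain. Of 17 dendritic cell and MHC class II genes, 11 rose and 0 fell (13 and 0 adjusted over the list alone; median 0.97, adjusted p = 1.10e-08, and adjusted p = 0.134 with an estimated correlation). Cd74, the invariant chain, went from 299 ± 56.7 to 610 ± 85.1 CPM. Of 19 MHC class I and antigen processing genes, 13 rose and 0 fell (15 and 0 adjusted over the list alone; median 0.92, adjusted p = 9.36e-10, and adjusted p = 0.101 with an estimated correlation). B2m, the light chain of class I molecules, went from 700 ± 113 to 1493 ± 200 CPM; values of the RT1 genes, such as RT1-A2 (1.44 ± 0.17) and RT1-Da (1.09 ± 0.16), are uncertain because near-identical copies share reads.

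Of 48 interferon response genes, 24 rose and 0 fell (32 and 1 adjusted over the list alone; median 0.75, adjusted p = 1.04e-14, and adjusted p = 0.101 with an estimated correlation). Gbp2, an interferon-induced GTPase, went from 17.5 ± 2.10 to 40.1 ± 2.31 CPM, and Ifi47, Ifi27 and Ddx58 (the RNA sensor RIG-I) rose by 1.16 to 1.26 on the log2 scale. Of 28 cytokines and chemokines, 8 rose and 1 fell (10 and 1 adjusted over the list alone; median 0.36, adjusted p = 0.000682, and adjusted p = 0.271 with an estimated correlation; median 0.55 without young replicate 2). Ccl24, a chemokine for eosinophils, rose by 2.28 ± 0.31, Ccl7 by 1.74 ± 0.26, Il33 by 1.13 ± 0.16 and Csf1 by 1.09 ± 0.15 on the log2 scale. Il18, named after its value was seen, fell by 2.13 ± 0.42. Of 9 neutrophil markers, 5 rose and 0 fell (5 and 1 adjusted over the list alone; median 1.30, adjusted p = 0.0190, and adjusted p = 0.214 with an estimated correlation). These were Mpo (3.77 ± 0.81), Ncf4 (1.48 ± 0.24), Csf3r (1.30 ± 0.29), Retnlg (1.92 ± 0.50) and Lcn2 (1.99 ± 0.57, named after its value was seen). The neutrophil list did not pass without old replicate 1 (adjusted p = 0.0570), with library totals alone (0.0581) or with the muscle score as covariate (0.119). Lcn2 was at 33.1 CPM in old replicate 3 and at 3.32 to 8.48 in the other old samples, and its log2 fold change was 1.00 without that library. Retnlg lost its call without young replicate 1, 3 or 4 or old replicate 1 or 4 (adjusted p up to 0.0824), and Lcn2 without any young replicate or old replicate 3 (up to 0.105). Of 8 erythroid and blood genes, 6 rose, among them the haemoglobin genes Hbb, Hba2 and Hbb-b1, whose copies share reads, and the platelet gene Pf4 (2.09 ± 0.35). The erythroid gene Epb42, named after its value was seen, was lower (-1.42 ± 0.41, adjusted p = 0.0454) but lost its call without any of the libraries except old replicate 3 (up to 0.104). The counts for this list were the same adjusted over the list alone (median 1.78, adjusted p = 0.00109, and adjusted p = 0.296 with an estimated correlation; 0.0520 with the muscle score as covariate).

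Matrix genes rose in part. Of 39 elastic fibre, proteoglycan and collagen assembly genes, 20 rose and 0 fell (23 and 0 adjusted over the list alone; median 0.67, adjusted p = 2.39e-10, and adjusted p = 0.101 with an estimated correlation). Fn1 (fibronectin) went from 140 ± 65.6 to 693 ± 189 CPM, Postn (periostin) from 189 ± 60.7 to 667 ± 116, and Loxl1, which cross-links elastin, from 27.8 ± 4.66 to 68.3 ± 13.9. Of 28 matrix proteases and inhibitors, 16 rose and 0 fell (22 and 0 adjusted over the list alone; median 0.74, adjusted p = 7.48e-10, and adjusted p = 0.101 with an estimated correlation). Adamts5, which cleaves aggrecan and versican, went from 9.33 ± 2.29 to 59.9 ± 19.97 CPM, and Mmp14, a membrane-bound collagenase, from 156 ± 18.6 to 282 ± 56.8. Of 21 collagens, 9 rose and 0 fell (11 and 0 adjusted over the list alone; median 0.78, adjusted p = 9.89e-06, and adjusted p = 0.214 with an estimated correlation), led by Col5a2 (1.04 ± 0.13), Col5a3 (1.96 ± 0.34), Col5a1 (0.79 ± 0.14) and Col14a1 (1.75 ± 0.35). With the adipocyte score as covariate the collagen list did not pass, and its median was 0.21 (adjusted p = 0.0797). The main collagens of dermis were not among them: Col3a1 stood at 2787 ± 349 and 3721 ± 447 CPM (0.42 ± 0.16, adjusted p = 0.124), and Col1a1 at 5465 ± 729 and 5134 ± 785 (-0.09 ± 0.18, adjusted p = 0.771). Col3a1 did not pass in 25 of 26 alternatives and passed in the other. The sign of the Col1a1 value turned with library totals alone (0.07) and without young replicate 4 (0.00473) or old replicate 4 (0.05). Of 17 fibroblast markers, 9 rose and 0 fell (11 and 0 adjusted over the list alone; median 0.71, adjusted p = 7.49e-05, and adjusted p = 0.143 with an estimated correlation). Pdgfra, a growth factor receptor of fibroblasts, went from 36.4 ± 9.76 to 119 ± 8.70 CPM and Dpt (dermatopontin) from 199 ± 35.9 to 682 ± 156.

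Lipid synthesis genes fell in part. Of 25 genes of cholesterol biosynthesis, 18 fell and 0 rose (22 and 0 adjusted over the list alone; median -0.996, adjusted p = 3.71e-10, and adjusted p = 0.208 with an estimated correlation). Lss (lanosterol synthase) went from 217 ± 56.3 to 68.9 ± 14.8 CPM, Cyp51 from 471 ± 137 to 191 ± 58.3, and Mvd from 86.6 ± 22.9 to 34.2 ± 11.5. Of 28 genes of the sebaceous gland and its lipid synthesis, 12 fell and 1 rose (13 and 2 adjusted over the list alone; median -0.86, adjusted p = 2.08e-05, and adjusted p = 0.366 with an estimated correlation). Scd1, a stearoyl-CoA desaturase, went from 1416 ± 475 to 318 ± 78.5 CPM; it and Scd (-1.25 ± 0.20) are close relatives that can share reads. Elovl6, a fatty acid elongase, fell by 3.09 ± 0.33 and Acly, which makes cytosolic acetyl-CoA, by 1.28 ± 0.21. The member that rose, named after its value was seen, was Acsl1 (1.23 ± 0.28), an acyl-CoA synthetase that fat cells also express. With the adipocyte score as covariate both lists passed at smaller medians, -0.56 for cholesterol (adjusted p = 0.0126) and -0.52 for the sebaceous list (adjusted p = 0.00559).

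Of 38 genes of epidermal differentiation and barrier, 13 fell and 1 rose (20 and 1 adjusted over the list alone; median -0.75, adjusted p = 2.65e-07, and adjusted p = 0.271 with an estimated correlation). The barrier list did not pass with the adipocyte score as covariate, where its median was -0.12 (adjusted p = 0.618). Tgm3 (transglutaminase 3) went from 382 ± 144 to 121 ± 10.2 CPM, Casp14 from 189 ± 65.1 to 36.8 ± 24.4 and Ivl (involucrin) from 292 ± 42.9 to 162 ± 28.4. The member that rose was the keratin gene Krt77, from 300 ± 88.1 to 4395 ± 3445 CPM, which did not pass with the muscle score as covariate. Old replicate 2 did not share its rise: it was at 361 CPM, within the young range of 216 to 431, and the other old samples were at 3076 to 8347. Of 15 genes of basal epidermis and hemidesmosomes, 1 fell, also adjusted over the list alone: Krt14, from 3542 ± 908 to 1813 ± 353 CPM, whose call was lost without young replicate 2 or 4 or old replicate 4 (adjusted p up to 0.0878). The list itself did not pass (median -0.21, adjusted p = 0.130).

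The mix of myosin heavy chain genes changed. Myh4 made up 2.43 ± 0.977% of the CPM of 4 adult myosin heavy chain genes in young skin (n = 5) and 87.4 ± 4.89% in old skin (n = 4), and Myh1, the type IIX gene, 83.9 ± 2.67% and 9.67 ± 4.71% (each two-sided exact permutation p = 0.00794). The summed CPM of Myh1, Myh2 and Myh4 was 15851 ± 6669 in young and 15966 ± 11009 in old skin. These genes are close paralogs in 1 cluster and can share reads, so the value of each is uncertain. Genes of slow fibres from other families fell: Tnnc1 by 4.23 ± 0.81, Tnni1 by 3.58 ± 0.61 and Myl2 by 3.66 ± 0.57 on the log2 scale. Myh7, the slow myosin gene, went from 779 ± 380 to 28.3 ± 41.3 CPM, but its call was lost without young replicate 2, 3, 4 or 5 or old replicate 1 (adjusted p up to 0.0847). Of 39 skeletal muscle markers, 8 fell and 1 rose (9 and 2 adjusted over the list alone; median -0.47, adjusted p = 0.000167, and adjusted p = 0.576 with an estimated correlation). The list's median ran from -0.15 without old replicate 3 to -0.96 without old replicate 2, and was -0.26 without young replicate 5 and -0.28 without old replicate 1. Its share of all counts varied widely in both groups, at 11.6 ± 4.02% in young and 9.53 ± 5.80% in old skin (two-sided exact permutation p = 0.508). With the muscle score as covariate, which is the mean of these same genes, the median was 0.59 (adjusted p = 0.000622). Of 70 nuclear-encoded genes of oxidative phosphorylation, 2 fell with edgeR, Ndufc1 and Atp5g3, and 0 adjusted over the list alone, while 52 were lower at an unadjusted p under 0.05 and DESeq2 called 22 lower (median -0.52, adjusted p = 4.83e-13, and adjusted p = 0.440 with an estimated correlation; 0.146 with the muscle score as covariate; median -0.33 without old replicate 3). Both genes lost their calls without any of the libraries except old replicate 2 (adjusted p up to 0.141).

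The pigment genes Tyrp1 and Dct were lower in all old samples than in any young one and very uneven in young skin. Tyrp1, an enzyme of melanin synthesis, had 110 and 62.1 CPM in young replicates 1 and 4, between 1.77 and 7.70 in the other young samples and at most 0.119 in the old ones. Its 3489 counts over the young libraries and 6 over the old give a pooled ratio of 756 (95% exact interval 347 to 2061, counting error only). Dct went from 52.2 ± 67.1 to 1.28 ± 0.691 CPM, and its call was lost without old replicate 3 or 4 (adjusted p = 0.0576 and 0.0712); neither gene passed with limma-voom (adjusted p = 0.105 for Tyrp1 and 0.127 for Dct). Of 9 melanocyte markers, these 2 fell and 0 rose (5 and 0 adjusted over the list alone; median -2.63, adjusted p = 0.0112, and adjusted p = 0.505 with an estimated correlation; median -2.74, adjusted p = 0.0733 with the adipocyte score as covariate). Hair shaft and inner root sheath genes spanned nearly the whole scale within both ages: the mean log2 CPM of 45 genes was 3.18 ± 4.46 in young and 2.95 ± 3.45 in old skin. With edgeR 0 rose and 0 fell, also adjusted over the list alone, at an unadjusted p under 0.05 and with DESeq2, and the list's median was -1.19 (adjusted p = 0.785). Of 62 cell cycle genes, 5 fell and 0 rose (4 and 0 adjusted over the list alone; median -0.62, adjusted p = 2.59e-07, and adjusted p = 0.567 with an estimated correlation). Aurka went from 99.7 ± 30.3 to 33.4 ± 13.5 CPM and Kif4a from 26.2 ± 6.39 to 9.51 ± 3.51; the others were Espl1, Tpx2 and, named after its value was seen, Kif20a. Espl1 was lost without young replicate 4 or old replicate 3 or 4 (adjusted p up to 0.0646), Tpx2 also without young replicate 2 (up to 0.0744), and Kif20a without young replicate 1, 2, 3 or 4 or old replicate 2, 3 or 4 (up to 0.131). The median was -0.34 without young replicate 1 and -0.40 without old replicate 4. With the hair score as covariate, 25 of the 62 fell, and with the adipocyte score the list did not pass (median -0.37, adjusted p = 0.659). The proliferation marker Mki67 stood at 86.2 ± 37.8 and 50.8 ± 17.7 CPM (-0.76 ± 0.35, adjusted p = 0.181). It did not pass in 24 of 26 alternatives and passed in the others.

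**Figure D2:**
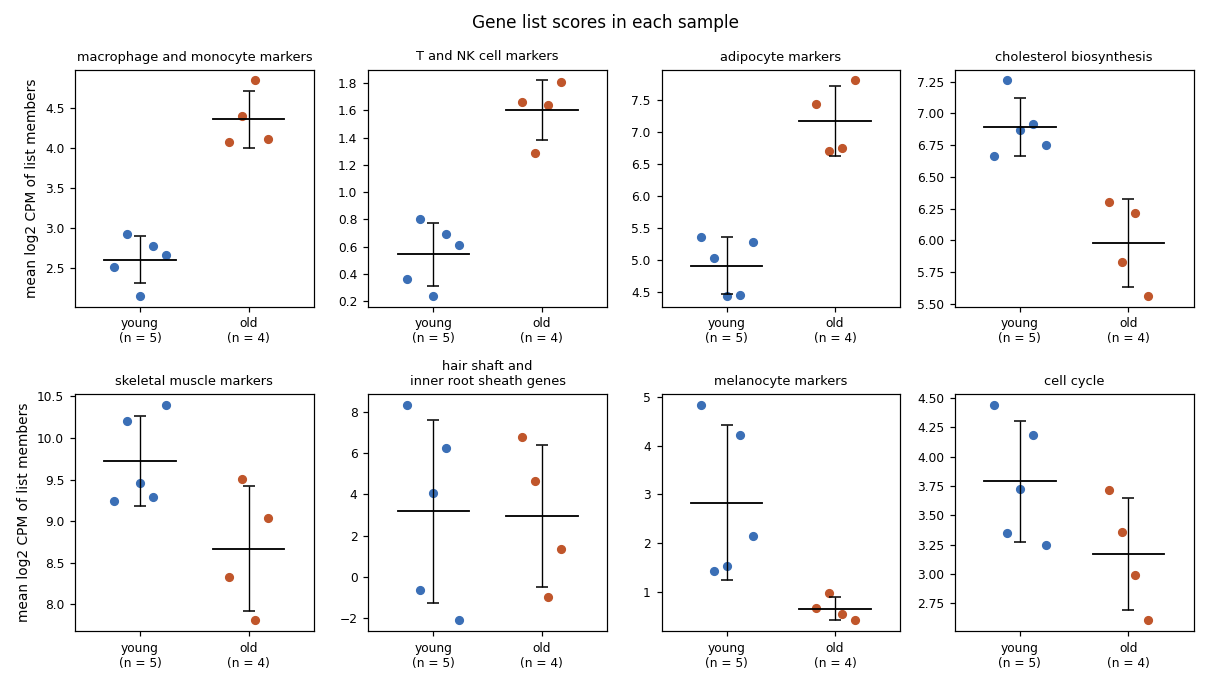
Mean log2 CPM of the members of 8 gene lists in each sample of young (blue) and old (orange) skin; lines are means and bars are 1 SD (n = 5 and n = 4). Macrophage scores were 2.60 ± 0.295 in young and 4.36 ± 0.357 in old skin, while hair shaft scores spread over both groups alike.

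Of the remaining lists, 3 passed the list test on small shifts. Of 66 cytosolic ribosomal protein genes, 1 rose, Rps9, which has near-identical copies and ranged from 1.11 to 130 CPM in the old samples; with edgeR 0 fell, over all genes and adjusted over the list alone (median -0.27, adjusted p = 9.51e-07, and adjusted p = 0.522 with an estimated correlation). At an unadjusted p under 0.05, 18 of the 66 were lower, and DESeq2 called 9 lower. Of 22 immediate early genes, Junb (-1.03 ± 0.21), Egr3 (-0.88 ± 0.18), Btg2 (-0.70 ± 0.14) and Myc (-0.38 ± 0.10, named after its value was seen) fell and Atf3 (1.33 ± 0.35) rose (5 and 2 adjusted over the list alone; median -0.42, adjusted p = 0.0112, and adjusted p = 0.271 with an estimated correlation). Myc kept its call only without young replicate 5 (adjusted p up to 0.173), and Atf3 lost it without young replicate 1, 2, 4 or 5 or old replicate 3 or 4 (up to 0.0701). Of 23 endothelial markers, 1 rose, also adjusted over the list alone: Pdpn (0.94 ± 0.17; median 0.36, adjusted p = 0.0328, and adjusted p = 0.645 with an estimated correlation). The endothelial list did not pass without young replicate 1 (0.192), old replicate 2 (0.312, median 0.20) or old replicate 4 (0.0958). With the adipocyte score as covariate none of these 3 lists passed: the medians were 0.0102 for ribosomal proteins (adjusted p = 0.610), -0.40 for immediate early genes (0.194) and 0.40 for endothelial markers (0.161).

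Another 10 lists did not pass. Of 16 Schwann cell and nerve markers, S100b (3.75 ± 0.49), Pmp22 (0.98 ± 0.15) and Gap43 (1.68 ± 0.40) rose, also adjusted over the list alone (list median 0.14, adjusted p = 0.209); S100b is also expressed by fat cells, and Gap43 was lost without young replicate 3 (adjusted p = 0.0527). Of 27 Wnt modulators, Frzb, a secreted Wnt antagonist, went from 1.59 ± 0.298 to 19.2 ± 4.51 CPM and Rspo3, a Wnt agonist, from 2.57 ± 0.727 to 0.658 ± 0.429, the same counts adjusted over the list alone (median -0.15, mean 0.20, adjusted p = 0.573). Of 37 antioxidant genes, 5 rose and 3 fell (6 and 5 adjusted over the list alone; median -0.32, adjusted p = 0.512). Sod3 (1.13 ± 0.18), Gpx7 (0.96 ± 0.19) and Gsta1, which has close copies, rose, as did, named after their values were seen, Gpx3 and Ephx1; Prdx2 (-0.80 ± 0.19) fell, as did, named likewise, Hmox1 and Prdx5. The calls of Gpx3, Ephx1, Hmox1 and Prdx5 were each lost without at least 6 of the 9 libraries in turn (adjusted p up to 0.147), and that of Prdx2 without young replicate 3 or 4 or old replicate 3 or 4 (up to 0.0669). Of 16 circadian clock genes, 2 fell, Bhlhe40 and RGD1566380 (3 adjusted over the list alone; median 0.02, mean -0.10, adjusted p = 0.512). Of 33 senescence genes, Eda2r rose and Bhlhe40 fell, the same counts adjusted over the list alone (median 0.02, adjusted p = 0.522); Eda2r was lost without young replicate 2, 3 or 4 or old replicate 4 (up to 0.0722). Cdkn2a, which encodes inhibitors of the cell cycle, was too low for the filter on counts, with 12 counts over the young and 100 over the old libraries (0.131 ± 0.0576 and 0.825 ± 0.388 CPM). In a fit of all 19484 genes with a count its log2 fold change was 2.59 ± 0.49 (adjusted p = 0.00909).

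Among 30 hair growth regulators, Igfbp5 rose (1.17 ± 0.25) and Tfap2a fell (-0.90 ± 0.20), the same counts adjusted over the list alone (median -0.45, adjusted p = 0.329); Tfap2a was lost without old replicate 4 (adjusted p = 0.0605). Of 21 bulge markers, Postn and Cd34 rose, also adjusted over the list alone (median -0.10, mean 0.09, adjusted p = 0.587); Cd34 (0.321 ± 0.101 and 0.817 ± 0.228 CPM) was lost without young replicate 3, 4 or 5 or old replicate 2, 3 or 4 (up to 0.0598). Of 16 smooth muscle and pericyte markers, Mcam rose (0.93 ± 0.17), also adjusted over the list alone (median -0.01, mean 0.05, adjusted p = 0.863). Of 7 B and plasma cell markers, Irf4 rose (1.52 ± 0.33), also adjusted over the list alone (median 0.23, adjusted p = 0.956). Of 26 protein folding genes, 0 passed with edgeR, also adjusted over the list alone; 1 was higher and 5 lower at an unadjusted p under 0.05, and DESeq2 called 4 lower (median -0.14, adjusted p = 0.299).

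**Figure D3:**
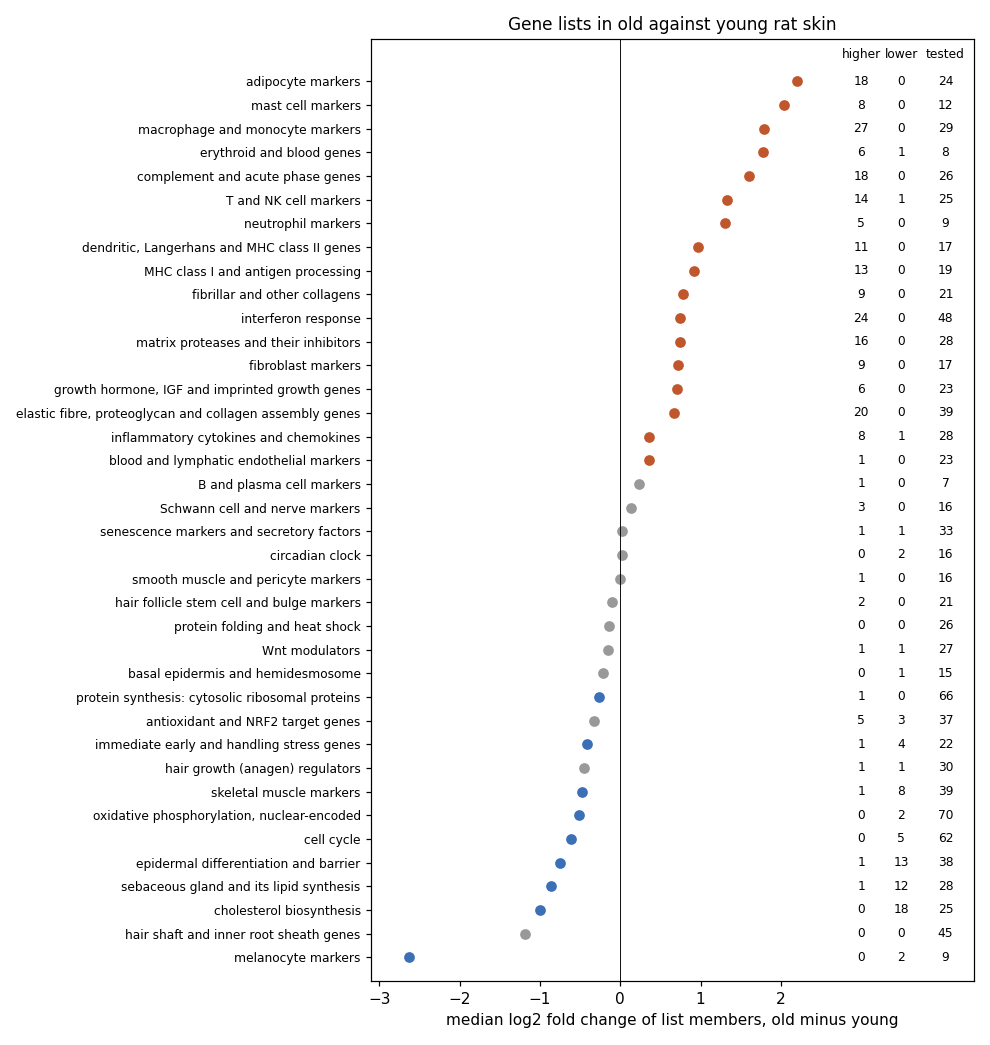
Median log2 fold change of each gene list, old minus young; orange lists rose and blue lists fell in the list test with a preset correlation, and grey lists did not pass. Columns give the members that rose, that fell and that were tested; 27 of 29 macrophage markers rose and 18 of 25 cholesterol genes fell.

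In all, 17 of the 38 lists tested rose and 9 fell with the preset correlation of 0.01. With an estimated correlation 0 lists passed in camera in either direction, and 11 were higher and 0 lower at an unadjusted p under 0.05. The method fry, which tests whether a list's genes move 1 way on balance, called 16 higher and 4 lower. Of 100 splits of the 9 samples into 5 and 4, the real one included, 10 called at least 26 lists, while 1 called as many genes. With the adipocyte score as covariate, medians of lists that still passed were lower for complement (1.14), T and NK cells (0.83), mast cells (1.07) and neutrophils (0.000522). Medians were higher for macrophages (2.41), cytokines (0.85) and erythroid genes (2.72), and that of skeletal muscle was -1.11. With the muscle score as covariate 1680 genes rose and 793 fell, and 1250 of the 2096 calls were kept in direction. Among the genes chosen by the rule or after their values were seen, those that did not pass with it were Kcnj3, Cdh16, Nhlh2, Myh7, Myh2, Myl3, Lum, Hoxb8, Aurka, Espl1, Tpx2, Mvd, Krt77, Hbb, Cd34, Junb, Atf3, Mpo, Csf3r, Lcn2, Ndufc1, Atp5g3, Cd6, Il18, Hmox1, Prdx5, Epb42, Myc and the placeholder locus RGD1563334 (adjusted p from 0.0504 for Kcnj3 to 0.438 for Lcn2). Genes that did not pass with library totals alone included Krt14, Prdx2, Tfap2a, Egr3, Atp5g3, Hmox1, Prdx5, Kif20a, Epb42, Hoxb8 and Myc. With limma-voom Mrgprg, Tyrp1, Dct, Rps9, Gap43, Atf3, Ephx1, Gpx3, Lcn2 and RGD1563334 did not pass.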

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

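Within a group, 15 of the 414 sets of 4 or 5 values tested held a sample far from the others (its gap to the nearest was most of the group's range); chance gives about 1 in 20, or more than were found. Among old samples, Mrgprg was at 14.6 CPM in replicate 2 against 0.948 to 1.28 in the others, and Tyr at 0.0528 CPM in replicate 1 against 0.463 to 0.593. In old replicate 3, Pf4 was at 33.3 CPM (12.7 to 14.4 in the others), Ifi27 at 138 (209 to 212) and Col5a1 at 219 (237 to 240). In old replicate 4, Scd was at 428 CPM (679 to 716), Mcam at 220 (131 to 143) and Prdx5 at 165 (172 to 173). Young replicate 3 was low for Col5a2 at 105 CPM (139 to 146 in the others) and Ctsk at 32.1 (43.5 to 47.5). Its scores, as mean log2 CPM, were also low for matrix proteases at 4.45 (4.71 to 4.81) and neutrophil markers at 1.43 (1.86 to 1.98). The score of matrix proteases was high in old replicate 1 at 5.74 (5.43 to 5.48), and that of protein folding genes in old replicate 2 at 7.20 (7.02 to 7.05). The locus LOC64038 was at 0.0570 CPM in young replicate 2 and at 0 in the other young samples, which is 1 count.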

How the results depend on the processing

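Thinned libraries and the muscle and hair scores together as covariates were chosen after seeing the data. The main test called 1437 genes higher and 659 lower. Genes higher in old skin numbered 702 at a threshold of 0.01, 506 with a change over 1.5-fold required and 2177 with the muscle and hair scores as covariates; genes lower in old skin numbered 138, 93 and 1438. Genes lower were 312 with library totals alone, 1270 with DESeq2, 1048 with limma-voom with sample weights and 1044 with the hair score as covariate. With the adipocyte score as covariate, whose values do not overlap between the ages, edgeR called 0 higher and 0 lower (smallest adjusted p 0.899), and 5 gene lists lower in old skin. Leaving out each library gave 1024 to 1573 genes higher, 236 to 786 lower, 16 to 17 lists higher and 9 to 10 lower. With an estimated correlation 0 lists were higher and 0 lower, and fry called 4 lower. Thinning to the smallest total left 1362 and 632 genes, so the greater depth of the old libraries alone did not set the counts. DESeq2 shared 2093 of the 2096 calls in direction.

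Replicate numbers did not pair the samples (correlations of same-numbered deviations 0.673, -0.0681, 0.0727 and -0.471), and a replicate block gave 1154 genes higher, 652 lower and 17 and 10 lists. Signs turned with the adipocyte score as covariate for Klf14 (-0.64), Pck1 (-1.17), Tmem179 (-0.43), Plin1 (-0.18), Mpo (-0.73), Retnlg (-0.17), Ephx1 (-0.14), Acsl1 (-0.46), Hmox1 (0.43), Rspo3 (0.0701), Hoxb8 (0.0834), Actn3 (-0.74), Mitf (-0.94), Col1a1 (0.0192) and the ribosomal protein list (0.0102). The Col1a1 value was 0.0727 with library totals alone, and ran from -0.162 to 0.0479 over the fits without 1 library, 0.00473 without young replicate 4. Acta1 was at 0.41 and Mitf at -0.27 with the muscle score and at 0.56 and -0.11 with the muscle and hair scores. Without 1 library Actn3 ran from -0.16 to 0.56 and Mitf from -0.13 to 0.35. The skeletal muscle list was at 0.59 with the muscle score and 0.72 with the muscle and hair scores as covariates, which hold the mean of its own genes. Of 153 called genes named, 126 stayed called in every fit without 1 library that tested them. Among these, Kcnj3 was tested in only 5 of the 9 fits. Apart from these constructions, the cause was not tested. In the simulation, which gave 132 calls, the test recovered 34% of 2-fold changes. The data gave 2096 calls, which makes the adjusted threshold less strict, so the share recovered there may be higher. A gene that did not pass may still have changed by 2-fold.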

Other observations

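The tests on muscle paralogs, on muscle share, on the share of other tissues and without 2 young libraries were chosen after the result was seen. The others were set before they were run. Those on body site and on hair growth phase concern patterns found in these data.

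Beside the fibre-type genes named by the rule, Myl3 (log2 fold change -3.08 ± 0.56, adjusted p = 0.00704) and Myoz2 (-3.15 ± 0.45, adjusted p = 0.00262), both named after their values were seen, fell in old skin with edgeR. Tnnt1 was at -3.91 ± 1.15 (adjusted p = 0.0504). It did not pass in 19 of 26 alternatives and passed in the others. Of 8 general genes of fast fibres or of all skeletal muscle 0 passed (adjusted p from 0.346 to 0.913): 6 were lower and 2 higher, from -0.85 ± 0.57 for Acta1 to 0.23 ± 0.51 for Actn3 (both named after their values were seen). Actn3 passed in some of the alternatives, and Acta1 in none. Of 27 tested genes that mark regions of the body, such as Hox genes, 3 rose and 1 fell. Tbx18 rose from 2.77 ± 0.947 to 8.496 ± 1.599 CPM, Hoxc9 from 1.93 ± 0.433 to 4.79 ± 1.28 and Hoxc8 from 13.3 ± 1.82 to 21.4 ± 2.09. Hoxb8 fell (-1.15 ± 0.32, adjusted p = 0.0394) and lost its call without young replicate 1, 3 or 4 or old replicate 1, 3 or 4 (adjusted p up to 0.131).

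Some loci with placeholder names, picked after their values were seen, were nearly absent at 1 age. RGD1562420 had 3194 counts over the young and 42 over the old libraries, RGD1564801 388 and 3, and LOC679755 361 and 3. Pooled ratios of young over old were 98.9 (95% exact interval 73.0 to 137), 168 (57.1 to 819) and 156 (53.1 to 762), for counting error only. The other way, LOC64038 had 1 count over the young and 113 over the old libraries (log2 fold change 5.98, adjusted p = 0.00170), and RGD1563334 was at 0.422 ± 0.384 CPM in young and 54.1 ± 76.3 in old skin (7.01, adjusted p = 0.0164). The latter ran from 0.154 to 164 CPM over the old samples and did not pass with limma-voom (adjusted p = 0.293) or with the muscle score as covariate (0.154). The annotation and counting rule are not given in the sources used here, so reads shared between copies may give such values, and the cause was not tested. Rps9, at 1.21 ± 0.441 CPM in young skin, was at 1.11, 130, 93.1 and 43.5 in the 4 old samples.

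The number of changed genes lay outside what other groupings of the samples gave: 1 of 100 splits into 5 and 4, the real one, called as many as 2096 genes, and the highest of the others called 145. The number of changed lists did not: 10 of the 100 splits called as many as the real 26, the highest of the others called 27 and their median was 16. Splits that called 26 or 27 lists had 0, 1, 3 or 4 old samples in the smaller group, so they kept part of the age contrast. Those with 2 old samples there, which are nearly balanced for age, called 4 to 21. The test with a preset correlation thus calls lists where little age contrast is left, so its adjusted p-values overstate the evidence for a difference by age. The number of lists therefore neither shows nor excludes chance. Members past the gene test carry the account of a list only where their share exceeds the 14.0% of all genes. It was smaller for oxidative phosphorylation (2 of 70), ribosomal proteins (1 of 66), endothelial markers (1 of 23) and cell cycle (5 of 62).

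Myh4 rose in old skin while Myh1 and genes of slow fibres fell, as did Myh2, which lost its call without young replicate 2 or old replicate 3 or 4 (adjusted p up to 0.0581). To weigh a lower share of muscle RNA, 6 slow-fibre genes were set against 31 other muscle genes. Their mean log2 CPM fell by 3.51 more (two-sided exact permutation p = 0.00794). The 6 were chosen after falls of slow-fibre genes were seen, so this p-value is no support and the difference does not decide on muscle share. Reads shared between myosin heavy chain paralogs are argued against only for these 6 genes themselves, which are of other families. Their median log2 fold change was -3.62, with 5 of them called. For Myh4 against Myh1 shared reads stay open: the summed CPM of Myh1, Myh2 and Myh4 did not separate the groups (two-sided exact permutation p = 1). A change from Myh1 to Myh4 would leave the sum level too, so the sum cannot decide. Skin from another body site, with another thin muscle sheet, may also differ this way, and it cannot be told apart from age here: 14.8% of 27 regional genes passed (exact 95% interval 4.19 to 33.7%) against 14.0% of other genes (one-sided Fisher exact p = 0.537).

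Most lists of immune cells and the fat cell list rose with a preset correlation, B and plasma cells not among them, and 0 lists passed with an estimated one. A lower share of muscle and epidermis would raise markers of all other cells alike. The macrophage score rose by 1.56 (mean log2 CPM) more than the mean of the endothelial, smooth muscle and Schwann scores (two-sided exact permutation p = 0.00794). This comparison was chosen after the rise of the macrophage list was seen, so its p-value is no support. It shows only that macrophage markers did not rise alike with those lists, and it does not cover fat cells or other immune cells. More subcutaneous fat with its usual immune cells was tested by the age effect on the macrophage score at a fixed adipocyte score, which was 2.18 (95% interval 0.643 to 3.71). The adipocyte scores of the ages do not overlap, so the value rests on 1 slope shared by both groups. Whether the groups share a slope was not tested. In young skin the lowest adipocyte score (4.44, replicate 3) came with the lowest macrophage score (2.15), but replicate 4 had 4.46 and 2.77. In old skin the highest adipocyte score (7.80, replicate 4) came with a macrophage score of 4.11, and replicate 3 had 6.75 and 4.85. The model therefore cannot tell fat content from age, and fat content stays open. Fat that holds more immune cells in old animals, and an effect of age on each tissue, stay open as untested hypotheses.

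Of the melanocyte markers, Tyrp1 and Dct fell. A difference in hair growth phase is argued against as the whole cause, since with the hair score as covariate Tyrp1 stayed lower (log2 fold change -8.73, adjusted p = 0.00342), as did Dct (-4.47, adjusted p = 0.00455). Without the 2 young libraries with very high values, with 3 young and 4 old samples, Tyrp1 was at -6.04 ± 0.85 (edgeR adjusted p = 0.0117) and Dct at -2.27 ± 0.46 (adjusted p = 0.0255). Both genes were chosen among genes whose groups do not overlap, so a fall was certain whichever libraries were left out. These p-values are therefore no support, and the sizes of the falls describe these 2 genes only. Pmel (-3.43 ± 1.09, adjusted p = 0.0651), Tyr (-4.90 ± 1.501, 0.0579) and Trpm1 (-2.63 ± 0.78, 0.0517) were lower without passing. Without those 2 libraries they stood at -1.03 to -0.81 and did not pass either (edgeR adjusted p from 0.230 to 0.502). With the hair score as covariate Pmel (-2.92, adjusted p = 0.0144) and Trpm1 (-2.01, adjusted p = 0.00948) passed. Mitf (0.04 ± 0.30) and Mlana (-0.78 ± 0.66), named after their values were seen, did not pass (adjusted p = 0.936 and 0.462), and without those libraries Mlana was at 0.74 ± 0.41, so a loss of pigment cells is neither shown nor excluded, and an effect of age or of another body site stays open.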
